A study of Mus musculus with 12 samples.

How the data were processed

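The series measured messenger RNA by bulk sequencing in 12 mouse libraries that fall into 4 groups of 3. Per the labels, GCaMP6s-expressing melanoma cells of the lines B16-F10 and B16-F10-OVA were grown as tumors in NOD-SCID mice, which lack their own T and B cells, and bead-activated CD8+ T cells of the OT-1 type were given afterwards. Tumors were taken 2 days after T cell transfer. The melanoma cells were sorted by fluorescence (FACS) for GCaMP6s, and the T cells were selected from the same kind of tumor with CD8 beads. The groups are named here by cell fraction and by the tumor line on the label: tumor cells labelled B16-F10, tumor cells labelled OVA, T cells labelled B16-F10 and T cells labelled OVA. The labels do not say whether the 3 libraries of a group came from 3 mice.

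The deposited table holds raw counts per Ensembl gene, with 1 column per library and no normalization. According to the processing notes, the authors aligned reads to the mouse genome build GRCm39 with HISAT2 2.0.5 and counted them with featureCounts 1.6.0. The strand setting, the handling of reads that map to several places and the annotation release are not stated there. The table lists 77175 genes, of which 21805 have no symbol. Genes were named by the symbols of the table, or by the Ensembl identifier where 1 symbol stood on several identifiers. No coordinates are given, because the reference at hand is of another build. Of 666 gene symbols in the gene lists, 659 were found. Every count column was used.

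Library totals ran from 15494683 to 33263730 counts. Levels are given as CPM, which scales each count by the total of its library and uses no TMM factor, as the mean ± SD of 3 libraries. Where all 3 libraries of a group had 0 counts, a fold is given as a lower bound against a floor of 3 counts over the group. Where a group held 1 to 3 counts, the ratio is given with its 95% Clopper-Pearson counting interval. Fitted fold changes of such genes depend on the prior count and are not printed for the comparisons within 1 cell fraction. Intervals and floors cover counting error only.

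Testing used R 4.3.3 with edgeR 4.0.16. Low counts were filtered with filterByExpr by group, libraries were scaled with TMM, and quasi-likelihood F tests were run with Benjamini-Hochberg adjustment and a threshold of 0.05. The OVA effect was fitted on the 6 libraries of each cell fraction. The difference between the OVA effects, and the difference between T cell and tumor cell libraries, were fitted on all 12 libraries. Standard errors (SE) of log2 fold changes were derived from the F statistic. Counts beyond 2-fold come from edgeR's glmTreat test against that fold, not from a filter on the estimate.

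Gene lists were tested with camera on the edgeR dispersions, with a preset inter-gene correlation of 0.01 and at least 4 measured genes, adjusted over the lists of a comparison. The lists, fixed before the data were examined, were: interferon gamma response, type I interferon response, MHC class I and MHC class II antigen presentation, mitotic and replication cell cycle, p53 and apoptosis, hypoxia, glycolysis, oxidative phosphorylation, unfolded protein and integrated stress response, cholesterol synthesis, immediate early genes, NF-kB and TNF response, and calcium entry and handling. Tumor cells also had melanocyte lineage, mesenchymal and dedifferentiation, and checkpoint ligands. T cells also had cytotoxic effector, inhibitory receptor and exhaustion, T cell receptor activation, naive and memory, T cell migration and cytoskeleton, and secreted T cell cytokines and chemokines. Marker lists covered T cell, melanoma cell, macrophage and monocyte, neutrophil, dendritic cell, NK cell, B cell, CD4 and regulatory T cell, fibroblast, endothelial cell, erythroid, keratinocyte, skeletal muscle and adipocyte. All 12 melanoma cell markers are also in the melanocyte lineage list. The T cell, macrophage and monocyte, fibroblast and endothelial cell markers share 0 genes with other lists, and 3 of the 12 NK cell markers are in other lists.

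The comparisons, tests, lists, named-gene rule and most alternatives were fixed before the data were examined. The rule named, for each OVA comparison, the 10 highest and 10 lowest log2 fold changes among called genes with a mean of at least 5 CPM in the higher group and no overlap between the libraries, leaving out predicted genes, clones, pseudogenes and unnamed identifiers. It also named up to 4 members per list with the smallest adjusted p, and a fixed set of anchor genes. For the comparisons over 12 libraries it named the highest 5 and lowest 5, plus Ptprc, Cd3e, Cd8a, Pmel, Tyrp1 and Dct in every library. The text uses a selection of these. Genes named outside the rule are said to have been chosen after their values were seen.

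Alternatives were median-ratio size factors, DESeq2 1.42.0, limma-voom (limma 3.58.1) with sample quality weights, no filter, a filter of at least 1 CPM in at least 3 libraries, the 2-fold test, 1 fit over all 12 libraries, a replicate block, leaving out each library, camera with an estimated correlation, and the fry rotation test. Scaling to the melanoma cell markers or to the T cell markers, and restriction to tumor-enriched genes, were added after seeing the data. The fits were tested on simulated counts drawn with the mean level of each gene over the libraries of a comparison, its fitted dispersion and the library totals, with planted changes. Changes of 1.5-fold, 2-fold and 4-fold were planted together, and each count of false calls covers the whole simulated set. At a true 2-fold change, 86.6% of 67 changed genes were recovered in tumor cells with 17 false calls among 16932 genes tested, and 83.6% of 67 in T cells with 16 false calls among 16234. For the difference of OVA effects 62.7% of 67 were recovered with 15 false calls among 17764, and for T cell against tumor cell libraries 85.1% of 67 with 9 among 17779. In both OVA comparisons the 1 changed list was called and 0 of 30 unchanged lists. The simulated genes were independent of each other and few were changed. False calls from correlated genes, or from a broad shift in cell composition, could therefore not show.

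Libraries of a group differed little beyond counting noise. For the 12 pairs of libraries within groups, chi-square over degrees of freedom was 1.51 to 1.77, over genes with an expected count of at least 10. Deviations from the group mean were correlated across genes between libraries that share a number. Over 12 pairs of groups and numbers r ran from -0.062 to 0.176, with genes not being independent replicates. The 2 pairs above 0.1 (0.176 and 0.128) were between tumor cells and T cells labelled OVA. Low values cannot exclude pairing where libraries differ by little more than counting noise. The numbers were not treated as pairing the libraries, because the labels do not say that they do.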

Results

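The 12 libraries form 4 groups of 3: melanoma cells sorted from B16-F10 or B16-F10-OVA tumors, and T cells selected from each kind of tumor. B16-F10 is a mouse melanoma line, B16-F10-OVA carries the model antigen ovalbumin, and OT-1 T cells bear a receptor for an ovalbumin peptide. Totals ran from 18948947 to 23213586 counts in tumor cells labelled B16-F10 and from 18754546 to 33263730 in those labelled OVA. They ran from 15494683 to 19296278 in T cells labelled B16-F10 and from 17203672 to 24267494 in those labelled OVA. Mitochondrial genes took 1.76% ± 0.0490 and 6.50% ± 0.0739 of the counts in tumor cells labelled B16-F10 and OVA, and 3.31% ± 0.0824 and 2.78% ± 0.0146 in T cells labelled B16-F10 and OVA. The ribosomal RNA gene Rn18s-rs5 took 0.559% ± 0.00695, 1.21% ± 0.0110, 1.05% ± 0.0320 and 0.316% ± 0.00227 in the same order. Differences in RNA quality or library preparation between the groups were not tested. Each p-value measures only the spread between these libraries, which may be technical, since libraries of a group differed by little more than counting noise.

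Pigment cell genes marked the tumor libraries and T cell genes the T cell libraries. Pmel, a melanosome protein, stood at 5361 ± 9.26 CPM in tumor cells labelled B16-F10 and 1925 ± 13.9 CPM in those labelled OVA, against 31.4 ± 0.742 and 20.3 ± 1.45 CPM in T cells labelled B16-F10 and OVA. The pigment enzyme genes Tyrp1 and Dct stood at 6696 ± 33 and 6722 ± 44.8 CPM in tumor cells labelled B16-F10, 3422 ± 16.9 and 2635 ± 0.731 CPM in those labelled OVA. T cells labelled B16-F10 had 80.5 ± 1.8 CPM of Tyrp1 and 88.5 ± 2.6 CPM of Dct, and T cells labelled OVA 26.0 ± 1.69 and 38.4 ± 3.07 CPM. Cd8a, the CD8 coreceptor chain, had 119 ± 1.34 and 129.9 ± 2.59 CPM in the T cell groups, 14.2 ± 1.03 CPM in tumor cells labelled OVA and 3 counts over the libraries of tumor cells labelled B16-F10. Cd3e, part of the T cell receptor complex, had 60.9 ± 1.02 and 75.1 ± 3.51 CPM in the T cell groups, 9.89 ± 0.777 CPM in tumor cells labelled OVA and 0 counts in those labelled B16-F10. Ptprc, the leukocyte surface protein CD45, stood at 0.398 ± 0.068 and 146 ± 2.73 CPM in the tumor groups and 375 ± 0.786 and 298 ± 4.96 CPM in the T cell groups.

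Markers of tumor stroma were abundant in the T cell libraries and in tumor cells labelled OVA. Endothelial cell markers summed to 44.2 ± 1.16 CPM in tumor cells labelled B16-F10, 4758 ± 30.9 CPM in those labelled OVA, and 11950 ± 35.3 and 11180 ± 38.9 CPM in T cells labelled B16-F10 and OVA. Fibroblast markers summed to 104 ± 3.26, 2970 ± 11.9, 8002 ± 79.7 and 7413 ± 65.3 CPM in the same order, and T cell markers to 7.45 ± 0.49, 283 ± 3.49, 1733 ± 7.92 and 1771 ± 2.75 CPM. Macrophage and monocyte markers were highest in tumor cells labelled OVA, with 537 ± 4.15, 3429 ± 10.5, 1030 ± 0.944 and 1009 ± 2.38 CPM. In tumor cells labelled B16-F10 only Apoe and Cd68 of the 18 macrophage and monocyte markers had at least 5 CPM, a count made after the values were seen. FACS for GCaMP6s would remove such cells from the tumor fraction, and CD8 beads would remove endothelial cells and fibroblasts from the T cell fraction.

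**Figure D1:**
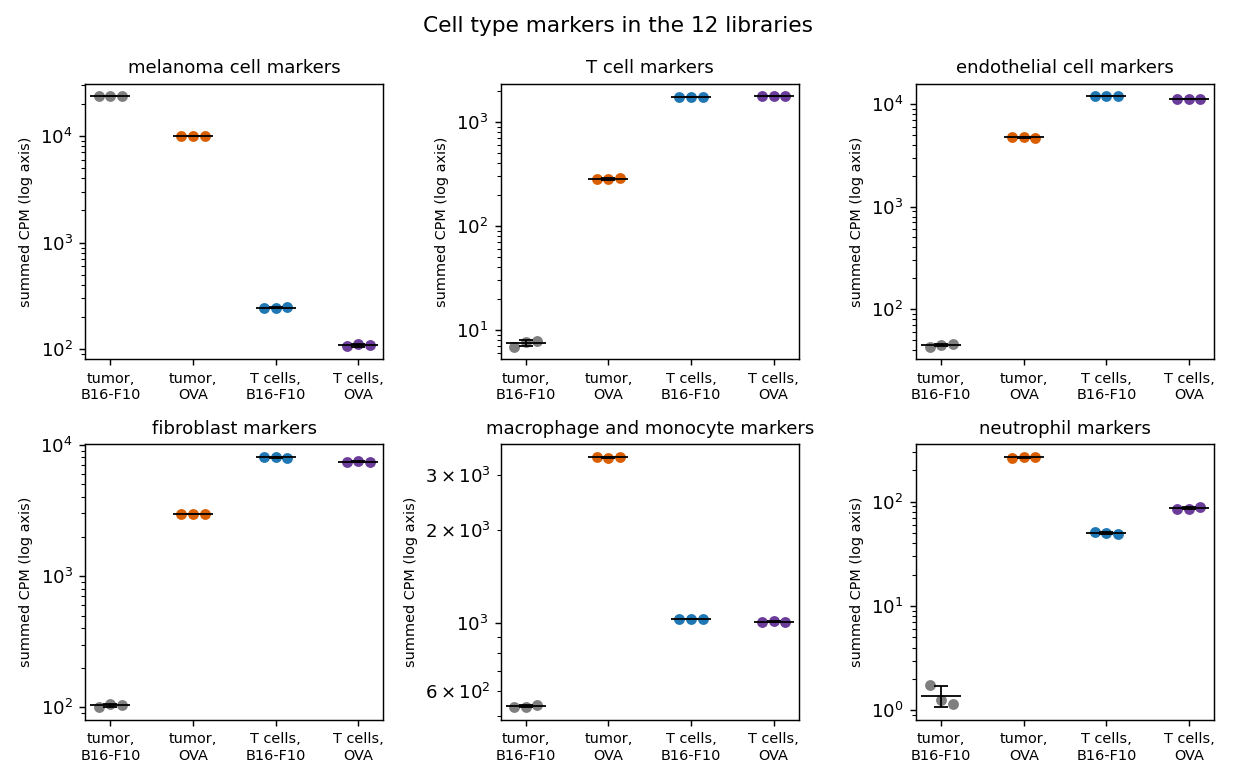
Summed CPM (log axes) of the markers of 6 cell types in the 12 libraries, with the mean and SD of each group of 3 in black. Endothelial markers reached 4758 CPM in tumor cells labelled OVA against 44.2 CPM in those labelled B16-F10.

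T cell libraries differed from tumor cell libraries, over both tumor lines, for 16070 of 18562 genes tested with edgeR. In T cell libraries 8499 were higher and 7571 lower, 4546 and 2705 of them beyond 2-fold. The highest were Ifng (interferon gamma), Trbc2 (a T cell receptor constant region), Emcn (an endothelial sialomucin), Pdcd1 (the inhibitory receptor PD-1) and Cyyr1. All 5 had 0 counts in tumor cells labelled B16-F10. Among the lowest, Ppargc1a, a coactivator of mitochondrial biogenesis, fell by 7.41 (SE 0.0362) on the log2 scale (adjusted p = 1.93e-38), and stood at 644 ± 14.5 and 339 ± 8.27 CPM in the tumor groups. Ankfn1 and Gpr158, a neuronal receptor, had log2 fold changes of -7.24 (SE 0.0675) and -7.50 (SE 0.198). Mtcl3 and Ott, the others of the lowest 5, stood at 15.7 ± 1.23 and 7.46 ± 0.548 CPM in tumor cells labelled B16-F10 and had 0 counts in T cells labelled OVA.

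Tumor cells labelled OVA held far more RNA of endothelial cells, fibroblasts, macrophages and T cells than those labelled B16-F10, and less RNA of pigment cell genes. Genes of NF-kB signalling, the immediate early response and antigen presentation rose. The sums of these lists were also higher in both T cell groups than in tumor cells labelled B16-F10. Whether melanoma cells or the other cells held the added RNA was not tested. The shares of mitochondrial and Rn18s-rs5 counts rose too, as given at the start. Genes of oxidative phosphorylation, cholesterol synthesis and glycolysis fell with TMM scaling, and interferon gamma response genes went both ways. With an estimated correlation 0 of 30 lists were called (smallest adjusted p = 0.216), and the oxidative phosphorylation and glycolysis medians turned to 0.52 and 0.52 under the melanoma marker scaling. Of 17418 genes tested with edgeR 7322 were higher and 6516 lower, 3867 and 797 of them beyond 2-fold. Scaling to the melanoma cell markers, chosen after seeing the data, shifted fold changes by 1.18 on the log2 scale and made 97.0% of 16287 calls higher, against 52.9% of 13838. Where no count over the list alone is given below, it equals the count over all genes. The direction of each OVA effect rests on the group labels, which the closing section weighs.

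Endothelial genes were among those with the highest fold changes, as was Inhbb, with a ratio of 26920 and a counting interval of 4832 to 1064000. Flt1 (ENSMUSG00000029648), a receptor for vascular endothelial growth factor, went from 0.0933 ± 0.0446 to 845 ± 7.22 CPM (log2 fold change 13.21, SE 0.0515, adjusted p = 2.57e-35, n = 3 per group). Kdr, a second such receptor, went from 0.0313 ± 0.0543 to 543 ± 5.24 CPM, a ratio of 17210 with a counting interval of 4763 to 142100. Emcn, Cyyr1 and the tight junction gene Cldn5 had 0 counts in tumor cells labelled B16-F10 and were at least 3012-fold, 2575-fold and 2543-fold higher. The junction genes Pecam1 and Cdh5 rose by 8.76 (SE 0.0384) and 12.75 (SE 0.0598) on the log2 scale. All 12 endothelial cell markers rose (median 10.84, or 10.75 with genes at the bound, adjusted p = 9.69e-09, and adjusted p = 0.216 with an estimated correlation). All 14 fibroblast markers rose (median 4.73, adjusted p = 1.98e-07, and adjusted p = 0.216 with an estimated correlation), with the collagen genes Col1a1 at 24.6 ± 1.65 and 659 ± 2.65 CPM and Col3a1 at 35.5 ± 2.19 and 736 ± 8.06 CPM.

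Immune cell markers rose with them. Of 18 macrophage and monocyte markers 17 rose and 1 fell (median 8.39, adjusted p = 3.59e-09, and adjusted p = 0.216 with an estimated correlation). The complement gene C1qa went from 0.209 ± 0.111 to 227 ± 0.62 CPM and the lysozyme gene Lyz2 from 1.73 ± 0.224 to 564 ± 7.8 CPM. All 20 T cell markers rose (median 7.96, or 7.41 with genes at the bound, adjusted p = 1.97e-07, and adjusted p = 0.216 with an estimated correlation). Trbc2 was at least 780.4-fold higher, and Cd8a had a ratio of 299 with a counting interval of 102 to 1452. All 10 neutrophil markers rose (median 8.19, or 6.16 with genes at the bound, adjusted p = 0.000115, and adjusted p = 0.227 with an estimated correlation), with the calprotectin gene S100a8 at 0.0607 ± 0.065 and 40.6 ± 2.01 CPM. All 13 dendritic cell markers rose (median 8.25, or 5.01 with genes at the bound, adjusted p = 1.46e-05, and adjusted p = 0.216 with an estimated correlation).

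Markers of further cell types were mostly higher, but only the NK cell and keratinocyte lists were called. All 6 measured NK cell markers rose (median 6.50, or 6.24 with genes at the bound, adjusted p = 0.0135, and adjusted p = 0.216 with an estimated correlation). All 7 keratinocyte markers rose (median 5.86, or 5.07 with genes at the bound, adjusted p = 0.00259, and adjusted p = 0.216 with an estimated correlation). Marker lists of B cells (4 higher and 2 lower of 7, median 5.46, or 3.66 with genes at the bound, adjusted p = 0.259), CD4 and regulatory T cells (4 higher and 0 lower of 4, median 1.98, adjusted p = 0.0721) and erythroid cells (4 higher and 1 lower of 5, median 8.44, or 5.61 with genes at the bound, adjusted p = 0.22) were not called. The skeletal muscle list (3 higher and 0 lower of 4, median 2.43, adjusted p = 0.149) was not called either. The adipocyte list had too few measured genes for a test, and its sum stood at 1.39 ± 0.223 and 334 ± 5 CPM. The beta globin gene Hbb-bs went from 0.0144 ± 0.0249 to 9.95 ± 0.128 CPM.

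Pigment cell genes fell. Of 12 melanoma cell markers 11 fell and 1 rose (median -1.18, adjusted p = 1.78e-07, and adjusted p = 0.216 with an estimated correlation). Slc24a5, a cation exchanger of pigment granules, fell by 2.09 (SE 0.019), and the channel gene Trpm1 by 1.37 (SE 0.0164) on the log2 scale. Pmel fell by 1.31 (SE 0.0118), and Dct by 1.18 (SE 0.0114), the latter to 0 under the melanoma marker scaling. Mitf, the master regulator of the lineage, fell by 0.38 (SE 0.0154) but was higher by 0.80 under that scaling. The wider melanocyte lineage list was 5 higher and 17 lower of 22 (median -0.97, adjusted p = 6.86e-06, and adjusted p = 0.216 with an estimated correlation). Its mean was 0.37, and its median was 0.21 when scaled. That scaling centres on the 12 melanoma cell markers, so it cannot test their fall. All 12, Dct and Mitf among them, are in the wider list. Its member Ednrb, an endothelin receptor that endothelial cells also express, went from 0.0978 ± 0.0942 to 312 ± 2.52 CPM.

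Interferon gamma response genes split, with 10 higher and 14 lower of 24. Their median was -0.54 and their mean 0.22, and the list was not called (adjusted p = 0.0605, downward). Igtp (ENSMUSG00000078853) and Irgm1, GTPases against intracellular pathogens, fell from 296 ± 4.5 to 39.5 ± 1.01 CPM and from 398 ± 4.35 to 71.4 ± 3.32 CPM. Outside the list, Apol6 and the guanylate-binding protein genes Gbp11 and Gbp10 were among the lowest 10 genes and fell by 5.21 (SE 0.13), 4.74 (SE 0.175) and 4.54 (SE 0.0693). Icam1, an adhesion protein, and Irf8, a myeloid transcription factor, rose by 8.44 (SE 0.0491) and 2.86 (SE 0.0354). Cd274, which encodes the ligand PD-L1, rose by 0.35 (SE 0.0231). The chemokine Cxcl10 rose by 0.16 (SE 0.0283) with TMM scaling. Its CPM did not rise (95.2 ± 0.974 and 94.4 ± 3.33 CPM) and overlapped between groups. Under the melanoma marker scaling 13 members were higher and 10 lower, with a median of 0.65. Type I interferon response genes were 17 higher and 10 lower of 27 (median 0.80, adjusted p = 0.0334, and adjusted p = 0.227 with an estimated correlation), with the antiviral regulator Irf7 up by 4.99 (SE 0.0913) and Rsad2 by 1.18 (SE 0.0285).

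Antigen presentation genes rose. MHC class I genes were 16 higher and 3 lower of 21 (median 0.60, adjusted p = 0.000319, and adjusted p = 0.216 with an estimated correlation). The heavy chain genes H2-K1 and H2-D1 went from 26.0 ± 1.1 to 542 ± 8.13 CPM and from 91.8 ± 1.3 to 1119 ± 4.85 CPM, and the light chain gene B2m rose by 1.54 (SE 0.0163). The T cell groups held 1362 ± 5.32 and 1346 ± 4.51 CPM of H2-K1. MHC class II genes were 10 higher and 1 lower of 11 (median 4.56, adjusted p = 0.000193, and adjusted p = 0.237 with an estimated correlation), with the invariant chain gene Cd74 at 45.1 ± 1.46 and 454 ± 8.69 CPM. Checkpoint ligand genes were 14 higher and 1 lower of 16 (median 1.56, adjusted p = 2.61e-05, and adjusted p = 0.216 with an estimated correlation), with Cd47, a brake on phagocytosis, up by 2.11 (SE 0.0268).

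Inflammatory and early response genes rose. All 20 NF-kB and TNF response genes rose (median 5.00, adjusted p = 2.64e-11, and adjusted p = 0.216 with an estimated correlation), the chemokine Cxcl2 by 8.46 (SE 0.0378) and the feedback inhibitor Tnfaip3 by 6.92 (SE 0.0311). Their sums were 334 ± 3.6 and 4069 ± 5.67 CPM in the tumor groups and 6106 ± 42.7 and 8049 ± 16.5 CPM in the T cell groups. Immediate early genes were 20 higher and 1 lower of 21 (median 3.12, adjusted p = 1.86e-10, and adjusted p = 0.216 with an estimated correlation), with the heat shock gene Hspa1a up by 9.04 (SE 0.0478) and Junb by 3.40 (SE 0.0216). Mesenchymal and dedifferentiation genes were 19 higher and 3 lower of 23 (median 2.86, adjusted p = 1.4e-06, and adjusted p = 0.216 with an estimated correlation). Among them the matrix genes Fn1 and Sparc rose by 2.63 (SE 0.0172) and 2.12 (SE 0.0134). Sparc had 5769 ± 33 and 5490 ± 33.4 CPM in the T cell groups, above 2782 ± 5.21 CPM in tumor cells labelled OVA. Calcium entry and handling genes were 23 higher and 7 lower of 34 (median 0.35, adjusted p = 0.0224, and adjusted p = 0.216 with an estimated correlation). The receptor gene Itpr3 rose by 3.37 (SE 0.0644), and the channel gene Vdac1 fell by 0.94 (SE 0.017) but was higher by 0.24 under the melanoma marker scaling.

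Metabolic and cell cycle genes fell with TMM scaling. All 33 oxidative phosphorylation genes fell (median -0.66, adjusted p = 1.53e-12, and adjusted p = 0.216 with an estimated correlation), Ndufa4 by 1.47 (SE 0.0197) and the ATP synthase gene Atp5f1b by 1.04 (SE 0.0125). The mitochondrial gene mt-Co1, chosen after its values were seen and not in the list, went up from 5628 ± 126 to 24940 ± 133 CPM, and the share of mitochondrial counts rose as given at the start. All 20 cholesterol synthesis genes fell (median -1.36, adjusted p = 2.81e-11, and adjusted p = 0.216 with an estimated correlation), with squalene epoxidase, Sqle, at 292 ± 1.17 and 73.5 ± 0.24 CPM. Glycolysis genes were 4 higher and 16 lower of 20 (median -0.66, adjusted p = 9.92e-06, and adjusted p = 0.216 with an estimated correlation), with Ldhb at -1.74 (SE 0.0181) and Gapdh at -0.90 (SE 0.0113). Cell cycle genes were 1 higher and 25 lower of 32 (median -0.27, adjusted p = 1.01e-05, and adjusted p = 0.216 with an estimated correlation), with the kinetochore gene Cenpf at -1.46 (SE 0.0465) and the proliferation gene Mki67 at -0.66 (SE 0.0191). Under the melanoma marker scaling the medians turned to 0.52 for oxidative phosphorylation, 0.52 for glycolysis and 0.92 for cell cycle, and Gapdh, Atp5f1b and Mki67 to 0.28, 0.14 and 0.52. The cholesterol median stayed below 0 at -0.18, with 8 members higher and 11 lower.

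Stress lists were not called: p53 and apoptosis (12 higher and 7 lower of 22, or 12 and 8 adjusted over the list alone, median 0.30, adjusted p = 0.388), hypoxia (12 higher and 9 lower of 22, or 13 and 9 adjusted over the list alone, median 0.19, adjusted p = 0.836) and the unfolded protein and integrated stress response (14 higher and 7 lower of 23, median 0.23, adjusted p = 0.172). Under the melanoma marker scaling all 22, 22 and 23 members of these lists were higher, with medians of 1.48, 1.38 and 1.41. Single members changed, with the hypoxia gene Ndrg1 up by 1.75 (SE 0.0216) and the stress gene Ppp1r15a up by 1.75 (SE 0.019). The remaining genes of the lowest 10 were Clvs1 (-6.96, SE 0.194), Dkk3 (-4.39, SE 0.0556), a secreted Wnt modulator, Gsta4 (-4.15, SE 0.0442), a glutathione transferase, Gfap, Mgarp and Mcoln3. Gsta4 went from 169 ± 5.36 to 8.54 ± 0.564 CPM. Mrap, an accessory protein of melanocortin receptors, was lower with a ratio of 211 with a counting interval of 57.9 to 1748. Of 30 lists camera called 22, 16 upward and 6 downward, and 0 with an estimated correlation (smallest adjusted p = 0.216). The unadjusted camera p was under 0.05 for 23 lists, and the fry rotation test called 30.

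**Figure D2:**
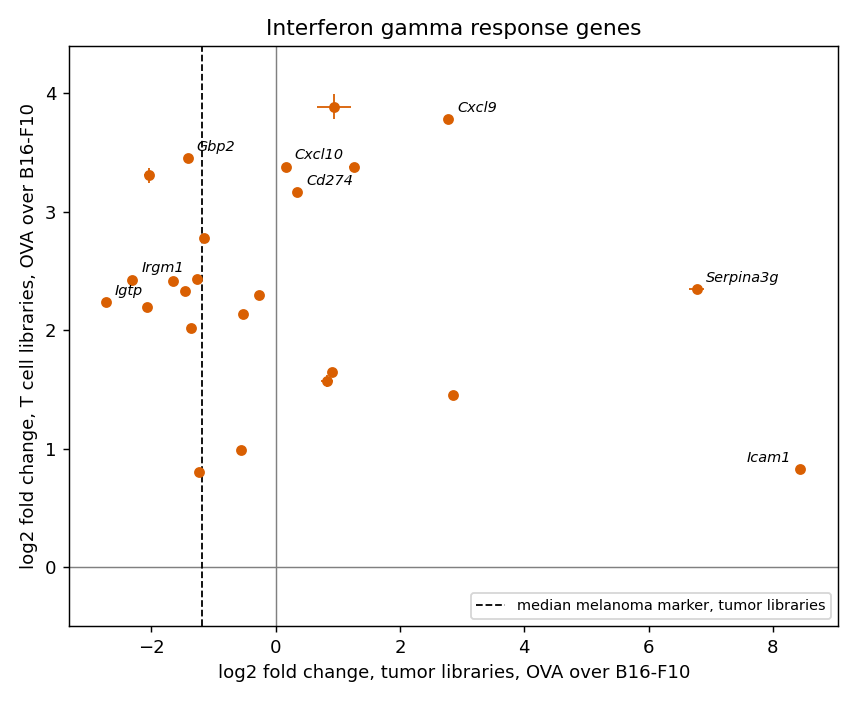
Log2 fold changes (OVA over B16-F10) of 24 interferon gamma response genes in tumor libraries and in T cell libraries, with standard errors. The dashed line is the median melanoma cell marker in tumor libraries; 14 genes were lower there, against 10 under the melanoma marker scaling.

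T cells labelled OVA had more RNA of cytotoxic effector genes, secreted cytokines and the interferon gamma response than T cells labelled B16-F10, at similar T cell marker levels. Their shares of mitochondrial and Rn18s-rs5 counts were lower, as given at the start. The T cell libraries also held much stromal RNA. Endothelial cell markers summed to 11950 ± 35.3 and 11180 ± 38.9 CPM there, against 1733 ± 7.92 and 1771 ± 2.75 CPM of T cell markers. Which cells carried the changes of genes that stromal cells also express was not tested. Ifng (ENSMUSG00000055170) went from 12.8 ± 0.79 to 315 ± 7.76 CPM (log2 fold change 4.67, SE 0.0368, adjusted p = 1.36e-33, n = 3 per group). Gzmb (ENSMUSG00000015437), the protease granzyme B, went from 129.7 ± 3.03 to 1624 ± 19.4 CPM (3.70, SE 0.0172), and Prf1, the pore-forming perforin, from 4.20 ± 0.179 to 86.8 ± 2.6 CPM (4.42, SE 0.0621). Tcf7, a transcription factor of naive and memory T cells, fell by 1.98 (SE 0.0498) and Tox, a regulator of exhaustion, by 2.85 (SE 0.266). Of 16536 genes tested with edgeR 3912 were higher and 3711 lower, 296 and 154 of them beyond 2-fold. Scaling to the T cell markers, chosen after seeing the data, shifted fold changes by -0.13 on the log2 scale and made 26.0% of 8723 calls higher, against 51.3% of 7623.

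**Figure D3:**
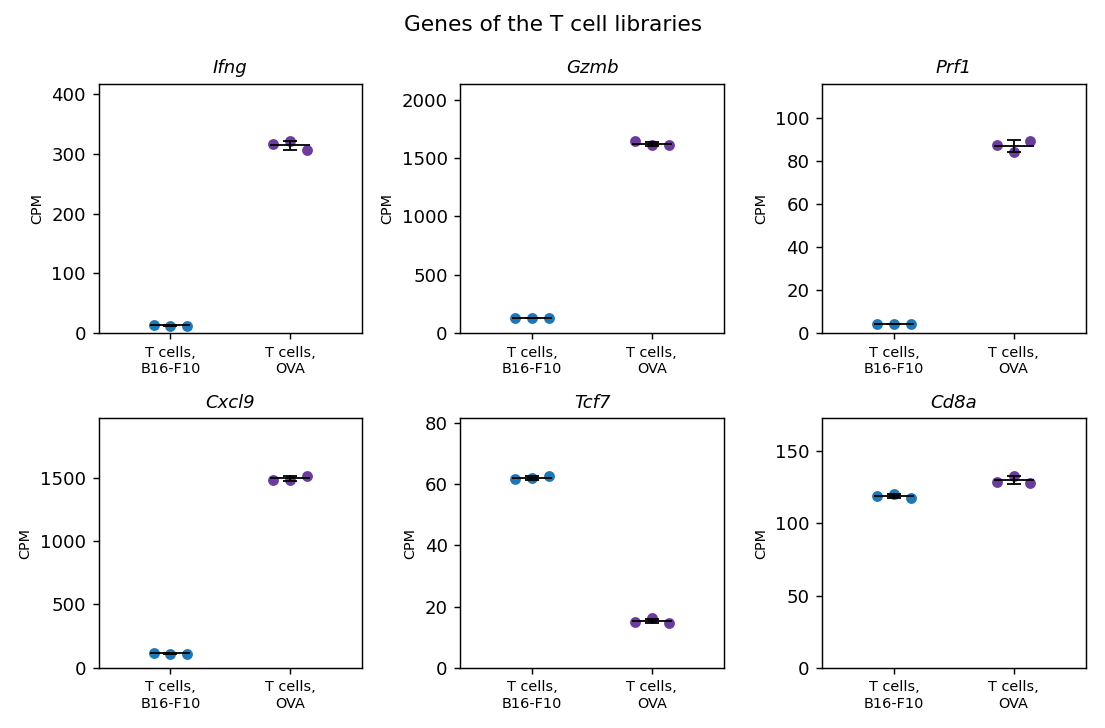
CPM of 6 genes in the 3 libraries of T cells labelled B16-F10 and the 3 of T cells labelled OVA, with the mean and SD in black. Ifng went from 12.8 to 315 CPM and Tcf7 from 62.1 to 15.2 CPM, while Cd8a stood at 119 and 129.9 CPM.

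All 25 interferon gamma response genes rose (median 2.35, adjusted p = 0.00483 with an estimated correlation). The chemokine genes Cxcl9 and Cxcl10 went from 113 ± 3.3 to 1493 ± 17 CPM and from 162 ± 3.88 to 1620 ± 9.1 CPM. The GTPase gene Gbp2 went from 186 ± 1.57 to 1962 ± 11.6 CPM and Cd274 from 90.0 ± 2.8 to 778 ± 4.25 CPM. The list summed to 3707 ± 8.97 and 17000 ± 30.5 CPM. All 27 type I interferon response genes rose (median 0.79, adjusted p = 1.11e-20, and adjusted p = 0.0317 with an estimated correlation), with the antiviral genes Rsad2 and Oasl2 up by 1.40 (SE 0.0304) and 1.24 (SE 0.0294). All 21 MHC class I presentation genes rose (median 0.38, adjusted p = 6.87e-18, and adjusted p = 0.0317 with an estimated correlation), led by the peptide transporter gene Tap1 (1.25, SE 0.0167). Under the T cell marker scaling 16 of them were higher and 2 lower. MHC class II genes were not called (2 higher and 4 lower of 11, median -0.03, adjusted p = 0.498), with H2-Eb1 at -0.23 (SE 0.0229).

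Cytotoxic effector genes were 18 higher and 6 lower of 25 (median 1.10, adjusted p = 1.05e-40, and adjusted p = 0.0133 with an estimated correlation). The granzyme genes Gzma and Gzmd rose by 2.43 (SE 0.0287) and 4.90 (SE 0.104), while Eomes, a transcription factor of effector and memory cells, fell by 1.12 (SE 0.0597). Secreted cytokine and chemokine genes were 17 higher and 1 lower of 18 (median 1.19, adjusted p = 1.71e-21, and adjusted p = 0.0133 with an estimated correlation), with the chemokine genes Ccl4 and Ccl3 up by 2.51 (SE 0.0436) and 2.28 (SE 0.0326). T cell receptor activation genes were 14 higher and 5 lower of 22, or 15 and 5 adjusted over the list alone (median 0.44, adjusted p = 2.8e-10, and adjusted p = 0.0317 with an estimated correlation). Il2ra, the interleukin 2 receptor alpha chain, went from 81.2 ± 0.901 to 347 ± 3.68 CPM and the costimulatory receptor gene Tnfrsf9 from 56.0 ± 1.97 to 234 ± 2.99 CPM. Nr4a1, an early gene of receptor signalling, fell by 0.75 (SE 0.0146), and Cd69, an early activation protein, rose by 0.46 (SE 0.0362). Nr4a1 went from 815 ± 8.46 to 467 ± 4.39 CPM. It also stood at 253 ± 1.65 and 827 ± 1.67 CPM in tumor cells labelled B16-F10 and OVA, so its fall cannot be assigned to T cells.

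Inhibitory receptor and exhaustion genes were 11 higher and 6 lower of 19 (median 0.21, adjusted p = 0.000695, and adjusted p = 0.0463 with an estimated correlation). Their median was 0.08 under the T cell marker scaling. Havcr2, which encodes TIM-3, rose by 2.36 (SE 0.044), Lag3 by 1.87 (SE 0.0357), Ctla4 by 0.92 (SE 0.0193) and Pdcd1 by 0.48 (SE 0.029), while Tox went from 3.42 ± 0.167 to 0.475 ± 0.247 CPM. Naive and memory genes were 4 higher and 11 lower of 18, or 5 and 11 adjusted over the list alone (median -0.17, adjusted p = 0.0289, and adjusted p = 0.196 with an estimated correlation). Tcf7 went from 62.1 ± 0.577 to 15.2 ± 0.765 CPM, the lymphotoxin gene Ltb fell by 0.99 (SE 0.0503), and Bach2, a repressor that maintains naive and memory cells, rose by 1.07 (SE 0.0656). Migration and cytoskeleton genes were not called (11 higher and 15 lower of 36, or 13 and 15 adjusted over the list alone, median -0.01, adjusted p = 0.984, with fry upward). The chemokine receptor gene Cxcr3 fell by 1.27 (SE 0.0712), and Cxcr4 and the adhesion gene Cd44 rose by 0.33 (SE 0.0203) and 0.56 (SE 0.0192). Calcium entry and handling genes were not called (11 higher and 12 lower of 34, or 11 and 13 adjusted over the list alone, median -0.04, adjusted p = 0.88, mean 0.02). The kinase gene Camk4 rose by 1.16 (SE 0.0731), and Itpr3 fell by 0.76 (SE 0.0303). Under the T cell marker scaling 8 migration genes were higher and 21 lower, and 7 and 20 calcium genes.

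Genes of sugar use, p53 and NF-kB rose. Glycolysis genes were 17 higher and 2 lower of 20 (median 0.31, adjusted p = 6.17e-15, and adjusted p = 0.0317 with an estimated correlation), with hexokinase Hk2 and the glucose transporter gene Slc2a3 up by 1.24 (SE 0.0283) and 1.34 (SE 0.0292). Hypoxia genes were 15 higher and 3 lower of 22 (median 0.13, adjusted p = 1.22e-06, and adjusted p = 0.0395 with an estimated correlation). Under the T cell marker scaling the glycolysis median was 0.19 and the hypoxia median 0. Pfkfb3, an activator of glycolysis, went from 486 ± 7.33 to 1901 ± 10.4 CPM. The p53 and apoptosis genes were 17 higher and 0 lower of 22 (median 0.45, adjusted p = 7.12e-09, and adjusted p = 0.0231 with an estimated correlation), with the cell death gene Pmaip1 up by 1.11 (SE 0.0354). The NF-kB and TNF response genes were 16 higher and 2 lower of 20 (median 0.51, adjusted p = 2.3e-19, and adjusted p = 0.0317 with an estimated correlation), with the cytokine gene Il6 up by 0.63 (SE 0.0174).

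Proliferation genes fell and other metabolic lists were not called. Cell cycle genes were 2 higher and 20 lower of 32, or 2 and 22 adjusted over the list alone (median -0.21, adjusted p = 0.00278, and adjusted p = 0.0523 with an estimated correlation), with Mki67 at -0.62 (SE 0.026) and Cenpf at -1.37 (SE 0.0752). Immediate early genes were 8 higher and 12 lower of 21, or 9 and 12 adjusted over the list alone (median -0.12, adjusted p = 0.035, and adjusted p = 0.136 with an estimated correlation), with Ier2 at -0.58 (SE 0.0208) and Junb at -0.33 (SE 0.0123). Not called were oxidative phosphorylation (1 higher and 11 lower of 33, or 1 and 8 adjusted over the list alone, median -0.06, adjusted p = 0.418), cholesterol synthesis (6 higher and 0 lower of 19, median 0.08, adjusted p = 0.539) and the unfolded protein and integrated stress response (15 higher and 3 lower of 23, or 18 and 4 adjusted over the list alone, median 0.18, adjusted p = 0.0554). Under the T cell marker scaling these 3 lists had 0, 2 and 9 members higher and 25, 7 and 8 lower, with medians of -0.19, -0.05 and 0.05.

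T cell markers were not called (10 higher and 6 lower of 20, median 0.13, adjusted p = 0.539). Cd8a rose by 0.18 (SE 0.0245), a call lost under the T cell marker scaling, while Trbc2 fell by 0.54 (SE 0.0187). Melanoma cell markers were 1 higher and 10 lower of 11 (median -0.80, adjusted p = 0.000277, and adjusted p = 0.0456 with an estimated correlation), with sums of 246 ± 3.8 and 109.6 ± 3.17 CPM. Endothelial cell markers were 4 higher and 7 lower of 12 (median -0.11, adjusted p = 0.0289, and adjusted p = 0.205 with an estimated correlation), with Cldn5 at -1.20 (SE 0.0196). NK cell markers were 3 higher and 1 lower of 6 (median 0.33, adjusted p = 0.00425, and adjusted p = 0.0793 with an estimated correlation), and their members Gzma and Xcl1 are also expressed by CD8 T cells.

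Further marker lists were not called in T cells. Those of myeloid cells were macrophages and monocytes (3 higher and 11 lower of 18, median -0.20, adjusted p = 0.0721), neutrophils (7 higher and 0 lower of 9, median 0.86, adjusted p = 0.0721) and dendritic cells (2 higher and 8 lower of 13, median -0.28, adjusted p = 0.306), with Lyz2 at -0.53 (SE 0.0312) and the neutrophil gene S100a9 at 0.86 (SE 0.0588). Those of lymphocytes were B cells (1 higher and 1 lower of 5, median -0.25, adjusted p = 0.705) and CD4 and regulatory T cells (1 higher and 2 lower of 4, or 2 and 2 adjusted over the list alone, median -0.04, adjusted p = 0.984, test upward). Those of stroma were fibroblasts (2 higher and 9 lower of 14, median -0.12, adjusted p = 0.0602) and adipocytes (1 higher and 2 lower of 4, median -0.19, adjusted p = 0.537), with the pericyte gene Pdgfrb at -0.45 (SE 0.0185). The rest were erythroid cells (0 higher and 5 lower of 5, median -0.50, adjusted p = 0.154), keratinocytes (1 higher and 4 lower of 5, median -1.96, adjusted p = 0.984, with fry upward) and skeletal muscle (0 higher and 3 lower of 8, median -0.62, adjusted p = 0.372). Cd4 itself stood at 14.4 ± 0.741 and 11.9 ± 0.333 CPM, and its call was lost without 1 library of either group and with DESeq2 (adjusted p = 0.0953).

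Ccl21a was among the 10 lowest genes. This chemokine gene had 25.9 ± 0.236 CPM in T cells labelled B16-F10 and 0 counts in those labelled OVA, at least 562-fold lower. Stab2, a gene of lymphatic and sinusoidal endothelium, had a log2 fold change of -2.44 (SE 0.184), and the hormone gene Fgf21 of -4.13 (SE 0.234). Zbtb32, a repressor in activated lymphocytes, rose by 4.88 (SE 0.0965) and the chemokine gene Cxcl11 by 3.89 (SE 0.107). Rn7s1 and Pagr1a had log2 fold changes of -3.47 (SE 0.402) and -3.33 (SE 0.519), and DESeq2 called neither (adjusted p = 0.386 and 0.105). Of 34 lists camera called 17, 12 upward and 5 downward. With an estimated correlation 12 of these held, and the 5 lost were cell cycle, immediate early, naive and memory, NK cell and endothelial cell.

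The OVA effect itself differed between T cell and tumor cell libraries for 12817 of 18562 genes in edgeR, being higher in T cells for 5147 and lower for 7670 (632 and 4338 beyond 2-fold). Interferon gamma response genes had the higher effect in T cells (21 higher and 3 lower of 25, median 2.81, adjusted p = 1.39e-52, and adjusted p = 0.00482 with an estimated correlation). Among single genes outside the list, Apol6 and Gbp10 had differences of 8.20 (SE 0.239) and 7.51 (SE 0.119) on the log2 scale. Cholesterol synthesis (19 higher and 0 lower of 20, median 1.40, adjusted p = 4.29e-11, and adjusted p = 0.00856 with an estimated correlation), glycolysis (16 higher and 4 lower of 20, median 1.08, adjusted p = 3.94e-13, and adjusted p = 0.0064 with an estimated correlation) and oxidative phosphorylation genes (30 higher and 1 lower of 33, or 31 and 1 adjusted over the list alone, median 0.56, adjusted p = 1.27e-06, and adjusted p = 0.0556 with an estimated correlation) also had higher effects in T cells. Markers had lower effects in T cells: all 12 of endothelial cells (median -10.87, adjusted p = 4.06e-83, and adjusted p = 0.00392 with an estimated correlation), all 14 of fibroblasts (median -5.04, adjusted p = 6.67e-38, and adjusted p = 0.00482 with an estimated correlation) and all 18 of macrophages and monocytes (median -8.51, adjusted p = 1.45e-33, and adjusted p = 0.0064 with an estimated correlation). So did all 20 T cell (median -7.86, adjusted p = 6.27e-06, and adjusted p = 0.163 with an estimated correlation), 10 neutrophil (median -7.21, adjusted p = 0.0333, and adjusted p = 0.0908 with an estimated correlation), 13 dendritic cell (median -8.22, adjusted p = 0.000109, and adjusted p = 0.0296 with an estimated correlation) and 4 adipocyte markers (median -7.90, adjusted p = 6.27e-06, and adjusted p = 0.0064 with an estimated correlation). The lower effects of these markers rest mostly on their rise in tumor cells labelled OVA. Fitted values of markers with a group at 0 depend on the prior count. The differences were fitted with TMM scaling only. In tumor cells the melanoma marker scaling turned the medians of oxidative phosphorylation and glycolysis to 0.52 and 0.52. It brought that of cholesterol synthesis to -0.18, so the higher effects of these lists in T cells may depend on the scaling. With the labels of the tumor libraries exchanged, which the closing section weighs, 7515 genes would be higher in T cells and 5328 lower, so the majority would turn. The medians would then be 10.86 for endothelial cells, 4.64 for fibroblasts, 8.16 for macrophages and monocytes, 8.16 for T cells, 9.11 for neutrophils, 7.88 for dendritic cells and 5.65 for adipocytes. Those of the interferon gamma response, cholesterol synthesis, glycolysis and oxidative phosphorylation would be 2.05, -1.25, -0.22 and -0.72, and Apol6 and Gbp10 would stand at -2.19 (SE 0.328) and -1.54 (SE 0.156). With the T cell labels exchanged instead, each of these signs turns.

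Response genes also had lower effects in T cells: NF-kB and TNF response (0 higher and 19 lower of 20, median -4.83, adjusted p = 6.4e-41, and adjusted p = 0.00644 with an estimated correlation), immediate early (0 higher and 20 lower of 21, median -3.04, adjusted p = 3.51e-51, and adjusted p = 0.0064 with an estimated correlation), MHC class II (1 higher and 10 lower of 11, median -4.74, adjusted p = 3.92e-13, and adjusted p = 0.0145 with an estimated correlation) and MHC class I genes (8 higher and 12 lower of 21, median -0.17, adjusted p = 7.4e-07, and adjusted p = 0.00896 with an estimated correlation). The median OVA effects of these 4 lists were 5.00, 3.12, 4.56 and 0.595 in tumor libraries. In T cell libraries they were 0.514, -0.123, -0.027 and 0.381. The differences thus rest mostly on rises in tumor cells labelled OVA, where RNA of other cells rose too. Whether that RNA accounts for them was not tested. With the tumor labels exchanged the medians of the differences would be 5.25, 3.08, 4.39 and 1.12. Not called were type I interferon response (12 higher and 13 lower of 27, median -0.01, adjusted p = 0.357, test upward), p53 and apoptosis (11 higher and 9 lower of 22, median 0.15, adjusted p = 0.334, mean -0.52) and hypoxia (9 higher and 11 lower of 22, median -0.14, adjusted p = 0.334, test upward). Nor were cell cycle (14 higher and 5 lower of 32, median 0.06, adjusted p = 0.154), unfolded protein and integrated stress response (9 higher and 13 lower of 23, median -0.12, adjusted p = 0.88), calcium handling (8 higher and 22 lower of 34, median -0.44, adjusted p = 0.17) and melanoma cell markers (4 higher and 2 lower of 12, median 0.08, adjusted p = 0.39). The markers of NK cells (0 higher and 6 lower of 6, median -6.67, adjusted p = 0.432), B cells (1 higher and 4 lower of 6, median -6.36, adjusted p = 0.186) and CD4 and regulatory T cells (0 higher and 3 lower of 4, median -2.06, adjusted p = 0.494) were not called. Those of erythroid cells (0 higher and 5 lower of 6, median -8.34, adjusted p = 0.327), keratinocytes (0 higher and 7 lower of 7, median -9.87, adjusted p = 0.327) and skeletal muscle (0 higher and 7 lower of 8, or 0 and 8 adjusted over the list alone, median -3.14, adjusted p = 0.578) were not called either. Of 28 lists 15 were called, and 12 of these held with an estimated correlation. With the tumor labels exchanged 19 lists would be called, and 12 with an estimated correlation. These 12 gain cell cycle (0 higher and 29 lower, median -0.42, adjusted p = 0.000124, and adjusted p = 0.00904 with an estimated correlation) and oxidative phosphorylation (adjusted p = 0.00904), and lose glycolysis and dendritic cells (adjusted p = 0.473 and 0.0594). Newly called, but only at the preset correlation, would be type I interferon response (25 higher and 0 lower, median 1.43, adjusted p = 8.08e-06, and adjusted p = 0.0927 with an estimated correlation), p53 and apoptosis (15 higher and 4 lower, median 0.68, adjusted p = 0.0105, and adjusted p = 0.0927 with an estimated correlation), hypoxia (15 higher and 6 lower, median 0.37, adjusted p = 0.0169, and adjusted p = 0.0927 with an estimated correlation) and melanoma cell markers (0 higher and 11 lower, median -2.20, adjusted p = 2.17e-05, and adjusted p = 0.0551 with an estimated correlation).

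The T cell libraries carried RNA of pigment cell genes, and tumor cells labelled OVA carried T cell RNA, so labels were compared across fractions with tests chosen after the values were seen. Tumor cells labelled B16-F10 had a T cell marker sum of 7.45 ± 0.49 CPM, too low for this comparison. Per 1000 CPM of summed T cell markers, Gzmb stood at 74.6, 74.8 and 917 CPM in tumor cells labelled OVA, T cells labelled B16-F10 and T cells labelled OVA. Ifng stood at 4.73, 7.38 and 178, Prf1 at 3.27, 2.42 and 49.0 and Il2ra at 47.0, 46.8 and 196 in the same order. Of 15 effector genes 11 were closer to T cells labelled B16-F10, with Ccl4, Tnf, Gzmg and Irf4 as exceptions. Across 74 genes enriched in tumor cells, the OVA effect in tumor libraries and that in the T cell libraries had r = -0.682, genes not being independent replicates. Over 6 settings, the median absolute deviation of log2 ratios between T cell and tumor libraries was lower with labels crossed in 6 for T cells labelled OVA and in 5 for T cells labelled B16-F10. The exception, with 17 genes, had 0.507 with the labels as given and 0.802 crossed, and at 22 genes they were close (0.48 and 0.47).

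**Figure D4:**
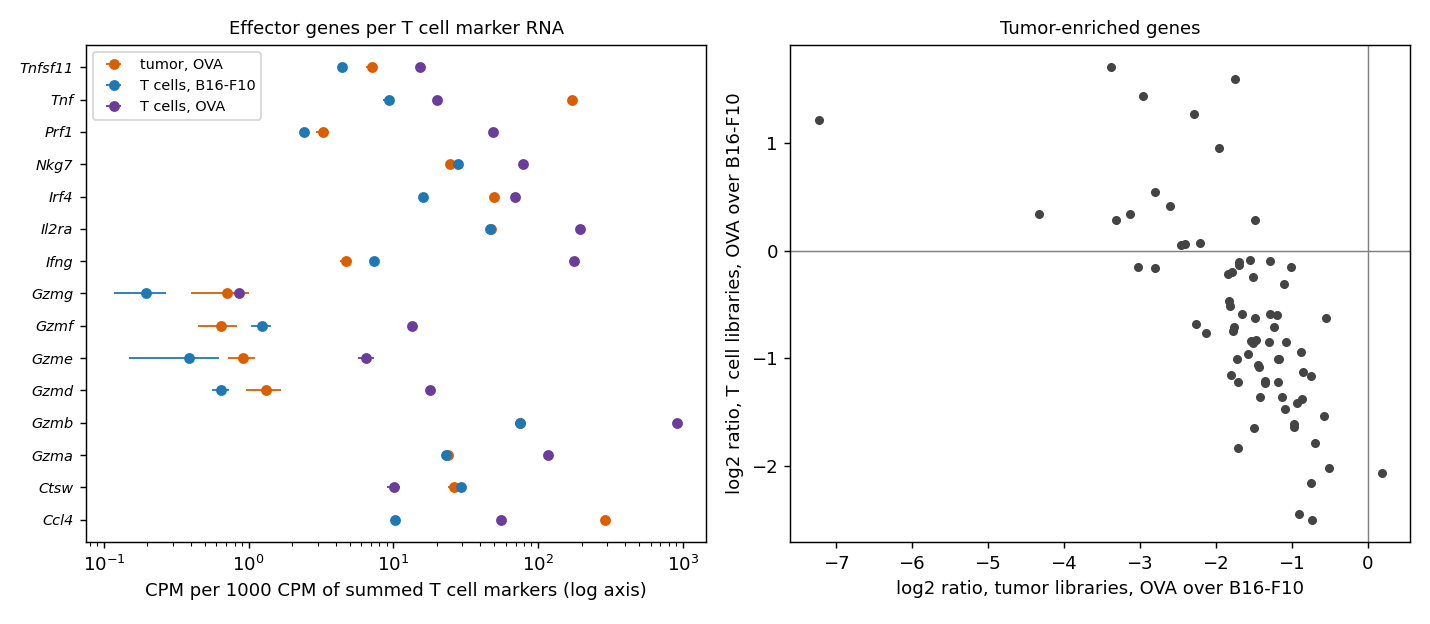
Left, 15 effector genes per 1000 CPM of summed T cell markers (log axis, mean and SD of 3 libraries), with Gzmb at 74.6, 74.8 and 917 in tumor cells labelled OVA, T cells labelled B16-F10 and T cells labelled OVA. Right, log2 ratios (OVA over B16-F10) of 74 tumor-enriched genes in tumor and in T cell libraries.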

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

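The tests of explanations below were all chosen after the result was seen, and the other splits of the libraries were chosen before it. For the residual melanoma and effector gene tests, the thresholds were also set after the values were seen and several forms had been looked at.

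The OVA effect differed between T cell and tumor cell libraries for 12817 genes. The highest differences on the log2 scale were those of Clvs1 (10.6), Apol6 (8.198), Gbp10 (7.509), Mrap (7.037) and Gbp11 (6.966). The lowest were Ccl21a (-21.41), Krt27 (-17.531), Krt71 (-17.396), Krt25 (-16.084) and Krt85 (-16.081), hair keratins apart from the chemokine Ccl21a. Fitted values of genes with a group at or near 0 depend on the prior count. Lists with a higher effect in T cells were interferon gamma response (median 2.814), cholesterol synthesis (1.398), glycolysis (1.083) and oxidative phosphorylation (0.561), the last not called with an estimated correlation (adjusted p = 0.0556). Lists with a lower one were MHC class I (-0.17) and class II antigen presentation (-4.741), immediate early genes (-3.039), NF-kB and TNF response (-4.833), and the markers of T cells (-7.859), macrophages and monocytes (-8.514), neutrophils (-7.212), dendritic cells (-8.221), fibroblasts (-5.045), endothelial cells (-10.874) and adipocytes (-7.895). With an estimated correlation the T cell and neutrophil markers were not called (adjusted p = 0.163 and 0.0908). The lower differences rest mostly on rises in tumor cells labelled OVA, where RNA of other cells rose too. NF-kB and TNF response genes, for example, rose in both fractions, with medians of 4.999 in tumor and 0.514 in T cell libraries. Whether RNA of other cells accounts for the differences was not tested. The differences were not fitted with the melanoma marker scaling. In tumor cells it turned the medians of oxidative phosphorylation, glycolysis and cholesterol synthesis to 0.524, 0.52 and -0.179. The directions of the differences also rest on the labels: with the labels of the tumor libraries exchanged, a calculation chosen after the result was seen, 7515 genes would be higher and 5328 lower in place of 5147 and 7670. Apol6, Gbp10, Mrap and Gbp11 would be at -2.191, -1.545, -7.463 and -2.485, and Clvs1 would not be called (adjusted p = 0.856). Ccl21a, Krt27 and Krt85 would not be called either (adjusted p = 1, 1 and 0.0702), and Krt71 and Krt25 would be at 6.155 and 6.078. The interferon gamma response median would stay higher at 2.049, while those of cholesterol synthesis (-1.248) and oxidative phosphorylation (-0.723) would turn lower and that of glycolysis (-0.225) would not be called. The medians of the lower lists would all turn higher, with endothelial cells at 10.857 and NF-kB and TNF response at 5.247, though T cell, neutrophil and dendritic cell markers would not be called with an estimated correlation (adjusted p = 0.188, 0.0927 and 0.0594). With the T cell labels exchanged instead, each of these signs turns.

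Tumor cells labelled OVA held RNA of endothelial cells, macrophages, fibroblasts and T cells, which FACS for GCaMP6s should remove: 56 of 64 measured markers, or 87.5%, were over 10-fold higher, and 11 of 12 melanoma cell markers were lower. RNA of the transferred T cells may account for the T cell part, with Trbv12-1 at 99.9% of the beta variable counts there. The hosts lack their own T cells, so a high share was likely beforehand. It also cannot separate T cells in the sort from carry-over of T cell libraries, which hold the same segment. The source of the other RNA in tumor cells labelled OVA was not tested separately. Against deeper sequencing, which CPM corrects for, the lowest endothelial sum in CPM among these libraries was 104 times the highest in tumor cells labelled B16-F10. Against carry-over of whole T cell libraries, the sums stood at 0.398 (endothelial), 0.371 (fibroblast), 0.163 (T cell) and 3.33 (macrophage and monocyte) times those of T cells labelled B16-F10. Whether these cells passed the sort or their free RNA did was not tested, and a difference between the tumor lines stays open.

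Interferon gamma response genes were lower in tumor cells labelled OVA for 14 of 24 members but higher in T cells labelled OVA for 25 of 25, and exchanged group labels in 1 cell fraction may explain this. Across 74 tumor-enriched genes the OVA effects in tumor libraries and in the melanoma RNA of T cell libraries had r = -0.682, with r from -0.717 to -0.586 over 6 settings of 17 to 128 genes, genes not being independent replicates, but with 17 genes the spread of log2 ratios to T cells labelled B16-F10 was lower with the labels as given (0.507 against 0.802). Per T cell marker, 15 effector genes in tumor cells labelled OVA had a median log2 ratio of -2.061 to T cells labelled OVA and 0.43 to T cells labelled B16-F10. Against dilution by other cells as the whole cause, 2 members, Igtp and Irgm1, fell below the lowest melanoma cell marker by more than 2 standard errors, but 2 are too few to exclude it. Which fraction would be exchanged cannot be told from these tests, and T cells that reached the tumor sort may differ in state from those taken with beads, which was not tested.

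Effector genes were higher in T cells labelled OVA, which may reflect recognition of ovalbumin if the labels hold. Against more T cells in these libraries, summed T cell markers had a ratio of 1.02. Against more NK cells, 7 NK cell markers summed to 1.34 ± 0.22 CPM in T cells labelled B16-F10 and 1.27 ± 0.0999 CPM in those labelled OVA. The latter sum was 0.0849% of the rise in Gzmb. That percentage alone cannot decide, since it depends on how abundant each transcript is in an NK cell. A difference between the tumor lines stays open and was not tested.

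With 6 libraries there are 10 splits, too few for a share under 0.05. The real grouping is itself counted among the splits and regroupings below. Every other split of 6 libraries mixes the 2 groups, which raises the spread within each, so few gene calls were likely beforehand. In tumor cells 1 of 10 splits gave as many genes as the real 13838, the highest other giving 0, and 1 of 10 gave as many lists as the real 22, the highest other giving 20. Each other split of the tumor libraries called at least 19 lists, so the list count at the preset correlation hardly depended on the grouping. In T cells 1 of 10 splits gave as many genes as the real 7623, the highest other giving 0, and 1 of 10 as many lists as the real 17, the highest other giving 14. Over all 12 libraries, 1 of 100 regroupings gave as many genes as the real 12817 for the difference of OVA effects, the highest other giving 10007. For T cell against tumor cell libraries 1 of 100 gave as many as the real 16070, the highest other giving 13099. Chance between mice is not excluded by these counts, since the labels do not say whether the libraries of a group came from 3 mice, and regroupings also mix the cell fractions.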

How the results depend on the processing

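Scaling to melanoma or T cell markers and the restriction to tumor-enriched genes were chosen after the results were seen, and the other alternatives before.

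In tumor cells 4664 genes passed the 2-fold test (glmTreat), and DESeq2 and limma-voom called 14385 and 13841. Among the 272 tumor-enriched genes 262 were called (13 higher, 249 lower), and 231 with scaling to the melanoma cell markers (128 higher, 103 lower). That scaling reversed Mitf to 0.804 (0.804 also among tumor-enriched genes), Mki67 to 0.521, Gapdh to 0.28, Atp5f1b to 0.142, Vdac1 to 0.242 and Ccng1 to 0.223. It set Dct to 0 in both settings, and Eno1 and Cenpe were no longer called (adjusted p = 0.866 and 0.287). Camera with an estimated correlation called 0 lists (smallest adjusted p = 0.216), with 23 lists at an unadjusted preset p under 0.05 and 30 called by fry.

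In T cells 450 genes passed the 2-fold test, DESeq2 and limma-voom called 6193 and 7600, and fry called 30 lists. Cd8a and Msn were not called with scaling to the T cell markers (adjusted p = 0.125 and 0.0622). Rn7s1, Pagr1a and Cd4 were not called by DESeq2 (adjusted p = 0.386, 0.105 and 0.0953). Cd4 was not called without T cells labelled B16-F10 replicate 1 (adjusted p = 0.0772) or T cells labelled OVA replicate 3 (adjusted p = 0.0523).

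For the difference of OVA effects 4970 genes passed the 2-fold test, and for T cell against tumor cell libraries 7251 did. With a replicate block, 13656 genes were called in tumor cells, 7576 in T cells and 12723 for the difference, with 23 and 18 lists in tumor and T cells. With a block of tumor model and number, 15949 genes differed between T cell and tumor cell libraries.

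Leaving out 1 library at a time gave 13528 to 14021 genes and 22 to 23 lists in tumor cells, and 6904 to 7186 genes and 16 to 19 lists in T cells. It gave 12581 to 12813 genes for the difference and 16050 to 16378 between T cell and tumor cell libraries.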

Other observations

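All tests and genes in this part were chosen after the values were seen.

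The T cell receptor was nearly uniform. Segment Trbv12-1 took 99.84% ± 0.0473 of the beta variable counts in T cells labelled B16-F10, 99.65% ± 0.150 in T cells labelled OVA and 99.90% ± 0.167 in tumor cells labelled OVA, with 35 segments annotated. Segment Trav14d-1 took 95.9%, 95.4% and 94.5% of the alpha variable counts, with 113 annotated. The T cell RNA in tumor cells labelled OVA thus had the same main segments as the transferred cells.

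Col4a1, a basement membrane collagen, stood at 15.6 CPM in tumor cells labelled B16-F10, 4179 CPM in those labelled OVA, and 11130 and 10890 CPM in T cells labelled B16-F10 and OVA. Igfbp3 stood at 0.450, 2309, 6305 and 5282 CPM in the same order. Xist, which marks female cells, stood at 0.756, 265, 536 and 554 CPM. The mitochondrial gene mt-Co1 stood at 5628, 24940, 12710 and 11730 CPM.

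Some genes had at least 20 counts in each of 2 groups and at most 2 elsewhere. Tumor cells labelled OVA shared 34 such genes with T cells labelled B16-F10 and 6 with T cells labelled OVA. Tumor cells labelled B16-F10 shared 2 with T cells labelled OVA and 1 with T cells labelled B16-F10.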
